A study of Drosophila melanogaster with 13 samples.

How the data were processed

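RNA was measured in 9 libraries of flow-sorted optic lobe clones at the wandering L3 stage, with 3 for each of the genotypes nerfin-1[159], lola[E76] and WT. Lola.N contact with DNA was measured in 2 Targeted DamID replicates (N1 and N2) of ey16F10-GAL4 cells. Per the labels' protocols, cells went straight into lysis buffer, sorts of different days were pooled into 3 samples per genotype of 33000 to 105000 cells (15 to 70 ng of RNA), and libraries were made with Lexogen QuantSeq. The authors' RNA table holds raw counts per gene, and the submitters' processing notes name Subread, featureCounts and limma without version or role. Each DamID file holds the authors' peak score, on a scale that is not given in the sources used here, and was called against Dam alone at an FDR of 0.01 per the file names. The Dam-only samples themselves were not analysed here. The build and annotation behind both kinds of file are not given in the sources used here. The last peaks on 3R and Y lie at 32.08 and 3.51 Mb, within the lengths of Release 6 of the fly genome. With the Release 6 gene table, 2778 of 17537 genes had an end within 1 kb of a peak of both replicates, against 2379 and 2356 when peaks were moved by 5 kb either way and 1919 and 1925 when moved by 100 kb. Of 17633 genes 33 carried no symbol, at most 0.0085% of the counts of a library.

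Samples were grouped by genotype as labelled, and all columns matched a labelled sample. Libraries held 3465601 to 5200223 counts, so that 3 counts, the floor used for folds against a group at 0, equal 0.577 to 0.866 CPM. Libraries of a group differed by at least 11 in chi-square per degree of freedom, so none duplicated another. Replicate numbers did not pair samples of different genotypes: deviations from the genotype mean correlated at -0.06 to 0.02 between libraries with the same number, and 1 of 9 libraries correlated best with its own number. Replicate number was therefore left out of the model and used as a replicate block in an alternative.

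Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 7451, and scaled by TMM. A quasi-likelihood model with 1 mean per genotype was fitted to all 9 libraries, and the 3 pairs of genotypes were tested two-sided at a Benjamini-Hochberg adjusted p of 0.05 with no minimum fold. Log2 CPM values carry a prior count of 2, while log2 differences are edgeR's fitted values with its own default prior. Of 22 gene lists fixed from general knowledge, holding 301 entries, 294 entries matched by the symbol in the file, 5 by a synonym and 2 by an older name. Lists were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, adjusted over the lists of a contrast, and called members were also counted after adjustment over the list alone. The Hox list of the central brain and nerve cord had 0 of 8 members tested. The correlation of both responses was set beside 50 simulations of unchanged groups, which have almost no calls and so give no expectation for shared calls. The plan was to keep the WT libraries, but a mean taken from them leaves no control error to share, so all 9 libraries were drawn from the mean over all libraries with the estimated dispersions. After the results were seen, the commitment list was tested again without the mutated genes lola and nerfin-1, and each mutant was also compared with WT libraries of its own, in an edgeR fit with 4 groups and 5 residual degrees of freedom, in which a lone WT library is taken to vary like the other groups.

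Peaks of both replicates were intersected, and overlap was compared with 1000 shuffles within chromosomes. A gene counted as bound when such an interval overlapped its body or 1 kb on either side. The plan had named 1 kb upstream and gene starts, but the reference carried no strand, so both sides and either gene end were used instead. Bound and called genes were compared by Fisher's exact test, two-sided, and by a Cochran-Mantel-Haenszel test in 5 bins of mean expression and 5 of gene length. Lists were compared with 10000 random lists matched on both. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

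Tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, apart from the departures on strand and on the simulated WT libraries and the tests named as later choices. The rule named lola, nerfin-1, chinmo, Imp, Syp, dpn, pros and elav always, the 6 largest called differences each way (4 between the mutants) among genes of mean log2 CPM of at least 3 with separate libraries and a gene symbol, and up to 3 called members per list. Of 182 pairs of named gene and contrast 166 were called, and 134 of these kept their call whichever library was left out. The other 32 are given in the text only for the fixed genes and for a few with the libraries named. Histone genes and Hsp70 copies share reads, and antisense or overlapping genes were treated as uncertain.

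Alternatives were size factors of DESeq2 1.42.0, library size only, no filter, a filter of 5 CPM in 3 libraries, DESeq2's Wald test, limma voom, fits on 2 groups only, the replicate block, leaving out each library, camera with an estimated correlation, the fry test, and for peaks those above the median score, reciprocal overlap of at least 0.5 of each peak, gene ends only, 5 kb on either side and each replicate alone. The pipeline was tested on simulated data before use. With 7183 genes it recovered 35.7% of 2-fold and 83.7% of 4-fold changes in simulated lola[E76] against WT groups with 4 false calls. It recovered 39.6% and 59.2% in simulated nerfin-1[159] against WT groups with 4 false calls, and 29.2% and 71.7% between the simulated mutants with 5. Calls planted in bound genes at 1.0 and 2.5 times the rate of other genes gave odds ratios of 0.832 (0.62 to 1.12) and 2.81 (2.26 to 3.50) within bins. Differences in isoform use and changes outside the counted 3′ tags were left out, since the table gives 1 value per gene.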

Results

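The data comprised 2 assays of the optic lobe, the visual centre of the larval *Drosophila* brain. Messenger RNA was counted by QuantSeq, which reads a short tag near the 3′ end of each transcript, in clone cells isolated by flow cytometry from wandering L3 larvae. Clones were WT, mutant for lola (allele lola[E76]) or mutant for nerfin-1 (allele nerfin-1[159]), with 3 libraries per genotype and 9 in all. Lola and Nerfin-1 are zinc finger transcription factors of postmitotic neurons that keep neurons from reverting to dividing neural stem cells (neuroblasts). Targeted DamID, in which a fusion of Dam methylase to the Lola.N isoform marks the DNA it contacts, was run in eyeless-GAL4 cells of the optic lobe at L3, with peak lists from 2 replicates (N1 and N2).

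The RNA libraries held 3754323, 4942596 and 5200223 counts in WT, 4191214, 4554654 and 4285823 in lola[E76], and 3465601, 4090627 and 3876453 in nerfin-1[159] clones. In these libraries 3 counts equalled 0.577 to 0.866 CPM (counts scaled to library size). Of 17633 genes in the table, 7451 had enough counts to be tested. Pearson's r of log2 CPM across genes was 0.947 to 0.963 between WT libraries, 0.905 to 0.935 between lola[E76] libraries and 0.934 to 0.942 between nerfin-1[159] libraries, against 0.85 to 0.927 between genotypes. The biological coefficient of variation was 24% in WT, 40.4% in lola[E76] and 30% in nerfin-1[159] clones. Replicate 1 of lola[E76] stood apart from the other 2 libraries of its genotype (40.4 on the third principal component, against -39.2 and -28.7). Each sample pooled sorts of different days and separate animals were not named, so p-values measure the spread between these samples.

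The mutated genes were examined first. The nerfin-1 tags numbered 1157, 1263 and 1452 in the WT libraries (283.6 ± 25.8 CPM, SD, n = 3) and 65, 27 and 8 in the nerfin-1[159] libraries (9.10 ± 8.38 CPM), a difference of -4.98 ± 0.36 (log2, SE; -5.97 without nerfin-1[159] replicate 1) with edgeR adjusted p = 4.16e-08. Here and below, edgeR adjusted p is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and log2 differences are given with their SE. Gene lists were tested with camera, which compares the members with all other genes. The lola tags were at 1763 ± 173 CPM in WT and 1984 ± 222 CPM in lola[E76] clones (log2 difference 0.17 ± 0.10, edgeR adjusted p = 0.414). Whether these 3′ tags lie within the part altered by the lola[E76] allele is not given in the sources used here, so they do not check that genotype.

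**Figure D1:**
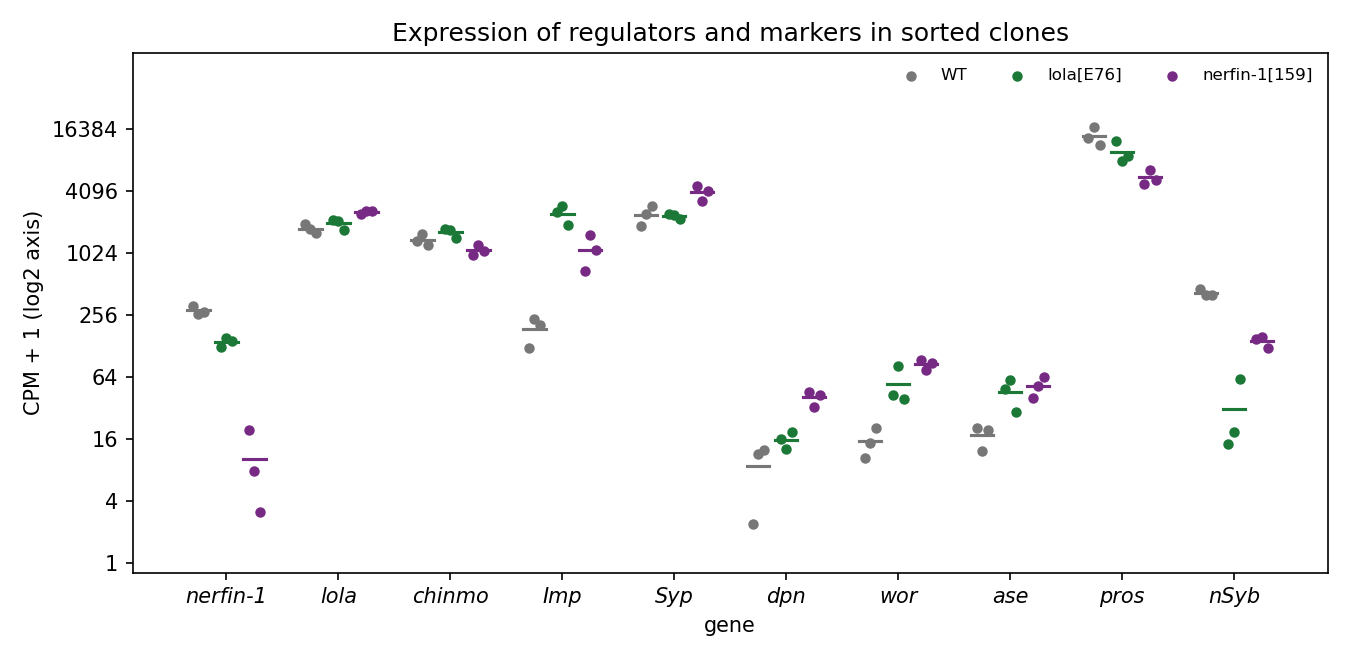
Expression of nerfin-1, lola, the temporal regulators chinmo, Imp and Syp, the neuroblast genes dpn, wor and ase, the differentiation factor pros and the synaptic gene nSyb, as CPM + 1 on a log2 axis. Points are single libraries (3 per genotype), bars are means, and Imp lies at a mean of 184.6 CPM in WT, 2470 CPM in lola[E76] and 1101 CPM in nerfin-1[159] clones.

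The first comparison asked which transcripts differ in optic lobe clones that lack Lola. The samples are sorted clones, and the WT libraries themselves held 5, 50 and 61 counts of the neuroblast gene dpn. Here and below, a changed share of progenitors and neurons therefore cannot be told apart from changes within neurons. Imp, an RNA-binding protein of young larval neuroblasts and early-born neurons, rose by 3.74 ± 0.26 (log2), from 184.6 ± 56.9 CPM in WT to 2470 ± 536 CPM in lola[E76] clones (SD, n = 3 each; edgeR adjusted p = 4.13e-08). The neuroblast transcription factors wor (1.89 ± 0.30, edgeR adjusted p = 0.0004) and ase (1.45 ± 0.30, edgeR adjusted p = 0.00479) rose as well, wor from 14.2 ± 5.06 to 53.1 ± 23.5 CPM. nSyb, a synaptic vesicle protein, fell from 415 ± 31.8 to 30.1 ± 25.6 CPM (log2 -3.78 ± 0.35, and -4.75 without lola[E76] replicate 3, edgeR adjusted p = 1.71e-06). chinmo, the BTB zinc finger factor in the title of the study, was at 1378 ± 174 CPM in WT and 1634 ± 185 CPM in lola[E76] clones and was not called (0.25 ± 0.12, edgeR adjusted p = 0.26).

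The other large rises in lola[E76] clones were of jef (4.19 ± 0.49, from 5.93 to 111 CPM; 4.80 without WT replicate 2), betaTub60D, a tubulin (3.65 ± 0.35), and Myd88, an adaptor of Toll signalling (3.48 ± 0.31). Others were Strn-Mlck, a relative of myosin light chain kinases (3.25 ± 0.14, from 132.4 ± 18.5 to 1256 ± 138 CPM) and GstE12, a glutathione transferase (3.18 ± 0.30). Their edgeR adjusted p lay between 1.67e-05 for jef and 1.98e-11 for Strn-Mlck. All of these genes lie on 2R, as does lola. A variant linked to lola[E76] on that arm therefore cannot be told apart from loss of Lola. Besides nSyb, the largest falls under the naming rule were of Actbeta, an activin ligand (-4.40 ± 0.70), and qvr, a regulator of potassium channels (-3.83 ± 0.37). Further falls were of Lcch3, a subunit of a ligand-gated ion channel (-3.57 ± 0.40), and Ca-alpha1D, a voltage-gated calcium channel (-3.38 ± 0.63), with edgeR adjusted p of 0.000462, 2.31e-06, 1.17e-05 and 0.00198. Without lola[E76] replicate 3, qvr was at -4.50 and Ca-alpha1D at -4.41. That library also held all 18 Actbeta counts of the genotype. Without it the group was at 0, at least 84.2-fold lower, and without lola[E76] replicate 2 the value was -3.80. Among 7451 tested genes, 484 were called, 267 higher and 217 lower, of which 185 and 106 changed at least 2-fold. The 3 libraries of one genotype lay wholly above those of the other for 24.8% of tested genes, where chance gives 10%, and for 473 of the called genes. Without WT replicate 1, and likewise without WT replicate 2, 315 genes were called.

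Neuronal groups were lower in lola[E76] clones. Of 23 tested neuron function genes, 5 fell and 0 rose (6 and 1 when adjusted over the list alone), among them VAChT, the vesicular acetylcholine transporter (-1.14 ± 0.19), and unc-13, a synaptic vesicle priming factor (-0.68 ± 0.11). The list median was -0.29 (camera adjusted p = 2.35e-05; adjusted p = 0.249 with an estimated correlation). Among 19 medulla neuron identity factors 5 fell and 1 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 4.11e-05; adjusted p = 0.056 with an estimated correlation). Their falls included the homeodomain factor Lim1 (-1.20 ± 0.15, edgeR adjusted p = 3.1e-05), the ETS factor Ets65A (-1.40 ± 0.20) and the COE factor kn (-1.36 ± 0.20).

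The temporal factors that pattern medulla neuroblasts shifted in both directions. Of 13 tested, 5 fell and 1 rose (7 and 1 when adjusted over the list alone). The homeodomain factor hth, which opens the series, rose by 0.80 ± 0.12 to 2043 ± 239 CPM (edgeR adjusted p = 0.000303), while hbn (-1.18 ± 0.21) and scro (-0.63 ± 0.12), which act later, fell. Their median was -0.63 (camera adjusted p = 0.00876; adjusted p = 0.304 with an estimated correlation). Among 6 early larval temporal factors, lin-28, an RNA-binding protein that blocks let-7 microRNA, went from 0 to 124 counts, at least 43-fold higher against a floor of 3 counts over the WT group (edgeR adjusted p = 0.00919; 0.0555, at least 25.7-fold, without lola[E76] replicate 1), and mamo fell by 0.65 ± 0.11. The list had 2 rises and 1 fall by either adjustment (camera adjusted p = 0.0738; 0.025 at the lowest, called without WT replicate 2 or lola[E76] replicate 3). Of 12 late temporal and ecdysone genes 1 fell by either adjustment, Eip93F (-1.03 ± 0.21), and 3 lay above WT. That list was not called (camera adjusted p = 0.595, median -0.04 with the test below 0). Such intervals and floors cover counting error only.

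Of 13 neuroblast genes 3 rose and 0 fell (5 and 0 when adjusted over the list alone; camera adjusted p = 0.000322; adjusted p = 0.056 with an estimated correlation). The third was mira, an adaptor of asymmetric division (1.23 ± 0.31, edgeR adjusted p = 0.0216), whose call was lost without lola[E76] replicate 2 or 3 (up to 0.0593), and with the DESeq2 Wald test or a fit on these 2 groups (up to 0.116). dpn, another neuroblast factor, was at 7.77 ± 5.59 CPM in WT and 14.7 ± 2.79 CPM in lola[E76] clones (edgeR adjusted p = 0.317). Of 16 Notch pathway genes, Notch itself (N, 0.88 ± 0.16, edgeR adjusted p = 0.00154) rose and E(spl)m6-BFM fell (-2.87 ± 0.58). Over the list alone 1 rose and 3 fell, and the list was not called (camera adjusted p = 0.228).

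Among 9 ganglion mother cell and commitment genes, nerfin-1 alone was called, at 139.1 ± 15.0 CPM against 283.6 ± 25.8 CPM in WT (-1.03 ± 0.28, edgeR adjusted p = 0.0342; 0 rises and 2 falls when adjusted over the list alone). That call was lost when any 1 of the 3 WT or 3 lola[E76] libraries was left out (adjusted p up to 0.121), and with library size only, the DESeq2 Wald test or the replicate block (up to 0.38). pros, the homeodomain factor that ends neuroblast divisions, was not called at 9888 ± 2440 CPM against 14030 ± 3010 CPM (edgeR adjusted p = 0.0639). It was called without WT replicate 3 or lola[E76] replicate 1 (0.00751 at the lowest), and with no filter or limma voom (1.83e-06 at the lowest). The list gave camera adjusted p = 0.0125 (adjusted p = 0.304 with an estimated correlation; 0.0592 without lola[E76] replicate 3). Without nerfin-1 and lola, the other 7 members had 0 calls (0 rises and 1 fall over the list alone; camera adjusted p = 0.0232; adjusted p = 0.304 with an estimated correlation). elav, a pan-neuronal RNA-binding protein, differed by -0.18 ± 0.10 (edgeR adjusted p = 0.378).

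For 18 S phase genes 0 were called by either adjustment, and 17 lay above WT with a median of 0.52 (camera adjusted p = 2.57e-05; adjusted p = 0.317 with an estimated correlation). Their most abundant member, E2f1, a transcription factor of S phase entry, differed by 0.15 ± 0.11 (edgeR adjusted p = 0.511). Of 19 G2 and mitosis genes 2 rose by either adjustment (camera adjusted p = 0.0431; adjusted p = 0.525 with an estimated correlation). This list call was lost without WT replicate 1, lola[E76] replicate 1 or 2, or nerfin-1[159] replicate 1 (up to 0.429). Of 16 nucleolus and growth genes 1 rose (3 when adjusted over the list alone) and 15 lay above WT (camera adjusted p = 0.0016; adjusted p = 0.249 with an estimated correlation). Of 12 glycolysis genes Gapdh1 (0.83 ± 0.14) and PyK (0.90 ± 0.18) rose, with 4 rises and 2 falls over the list alone (camera adjusted p = 0.167). Of 18 oxidative phosphorylation genes 0 were called by either adjustment (camera adjusted p = 0.03; adjusted p = 0.304 with an estimated correlation). This list call was lost without WT replicate 1 or lola[E76] replicate 1 or 3 (up to 0.151). Of 21 axon guidance and adhesion genes DIP-alpha rose (1.06 ± 0.22) and Sema1a (-0.62 ± 0.11) and Nrt (-0.77 ± 0.14) fell, the same count when adjusted over the list alone (camera adjusted p = 0.167).

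Genes of damage and cell death were higher, with 4 of 11 JNK, damage and cell death genes rising and 0 falling (5 and 0 when adjusted over the list alone), including hid, a trigger of apoptosis (1.5 ± 0.21, edgeR adjusted p = 0.000152), and GstD1, an oxidative stress gene (1.85 ± 0.27). The list gave camera adjusted p = 6.82e-05 (adjusted p = 0.056 with an estimated correlation). Of 12 heat shock genes 3 fell by either adjustment, led by Hsp26 (-0.83 ± 0.14; camera adjusted p = 0.0206; adjusted p = 0.525 with an estimated correlation). This list call was lost without WT replicate 3 or lola[E76] replicate 2 (up to 0.273). The falls of Hsp70Aa and Hsp70Ab are uncertain, since these near-identical copies share reads. Both calls were also lost without WT replicate 1 or 3 or lola[E76] replicate 1 or 2 (edgeR adjusted p up to 0.104 and 0.118).

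The fixed lists of other cells held single changes in lola[E76] clones. The glial gene wrapper rose to 17.8 ± 8.44 CPM (3.95 ± 0.81; 4.61 without WT replicate 3), as 1 of 10 glial genes by either adjustment (camera adjusted p = 0.622, median -0.02 with the test above 0). Col4a1, a collagen of fat body and blood cells, rose to 29.4 ± 9.62 CPM (2.46 ± 0.33, edgeR adjusted p = 9.36e-05), as 1 of 4 haemocyte and fat body genes by either adjustment (camera adjusted p = 0.851). Among 9 neuroepithelium and lamina genes dac fell (-1.20 ± 0.22) and 1 rose, by either adjustment (camera adjusted p = 0.524, median -0.19 with the test below 0). Of 4 eye disc genes 0 were called (0 rises and 1 fall when adjusted over the list alone; camera adjusted p = 0.683). None of the 8 Hox genes of the central brain and nerve cord had enough counts to be tested in any comparison. The dosage compensation RNA roX1 was at 1159 ± 379 CPM in WT and 1399 ± 372 CPM in lola[E76] clones. The 2 roX RNAs had 0 calls (1 rise over the list alone; camera adjusted p = 0.121, and 0.0126 without WT replicate 3).

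The second comparison asked the same of clones without Nerfin-1. Here dpn rose from 7.77 ± 5.59 to 39.5 ± 7.02 CPM (2.31 ± 0.46, edgeR adjusted p = 0.00186, n = 3 each), wor to 83.9 ± 10 CPM (2.55 ± 0.30, edgeR adjusted p = 1.14e-05) and klu, a neuroblast zinc finger factor, from 92.6 ± 55.9 to 562.8 ± 72.4 CPM (2.59 ± 0.32, edgeR adjusted p = 1.7e-05). Imp rose by 2.57 ± 0.25 to 1101 ± 427 CPM (edgeR adjusted p = 1.3e-06), and so did Syp, the RNA-binding protein of older neuroblasts that opposes Imp (0.72 ± 0.14, to 3988 ± 634 CPM, edgeR adjusted p = 0.00123). pros fell by 1.34 to 5549 ± 938 CPM (SE 0.16, edgeR adjusted p = 1.3e-05), and lola rose by 0.54 ± 0.10 (edgeR adjusted p = 0.00124). chinmo was at 1091 ± 123 CPM against 1378 ± 174 CPM in WT and was not called (edgeR adjusted p = 0.0713). It was called without WT replicate 3 or nerfin-1[159] replicate 2 (0.0366 at the lowest), and with no filter, limma voom or the replicate block (0.0219 at the lowest). elav differed by -0.09 ± 0.10 (edgeR adjusted p = 0.72).

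The largest rise under the naming rule was of Col4a1 (5.47 ± 0.34, from 5.09 to 236.2 CPM, edgeR adjusted p = 4.51e-09), followed by Rnf11 (3.16 ± 0.24), the lactate dehydrogenase Ldh (3.12 ± 0.58; 4.24 without WT replicate 2), the RNA-binding protein caz (2.96 ± 0.20) and the cell cycle brake trbl (2.65 ± 0.36). Among genes open to the naming rule (well expressed, with a symbol and separate libraries), the falls of ry, xanthine dehydrogenase (-6.24 ± 0.59, from 49.3 to 0.661 CPM, edgeR adjusted p = 1.04e-06), and nerfin-1 were the largest. All 7 ry counts of the mutant came from nerfin-1[159] replicate 1. Without it the group was at 0, at least 129-fold lower, and without nerfin-1[159] replicate 2 the value was -5.64. This gene lies in a run of large falls on 3R, described at the end. A variant on both 3R chromosomes of the nerfin-1[159] clones is a candidate for it. The next falls were of ImpE1, an ecdysone-induced gene (-3.56 ± 0.51; -2.35 without WT replicate 3), ap, a LIM homeodomain factor of medulla neurons (-3.45 ± 0.30), side-VIII, a cell adhesion protein (-3.21 ± 0.33), and Octbeta3R, an octopamine receptor (-3.09 ± 0.46). In all 889 genes were called, 422 higher and 467 lower, of which 235 and 275 changed at least 2-fold. The libraries of both genotypes lay wholly apart for 30.5% of tested genes, against 10% by chance, and for 874 of the called genes. Of 39 tested replication-dependent histone copies, which are near-identical and share reads, 28 were among the rises (median 1.70), leaving 394 rises without them.

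Of 13 neuroblast genes 10 rose and 0 fell (11 and 0 when adjusted over the list alone), with a median of 1.37 (camera adjusted p = 1.19e-10; adjusted p = 0.0106 with an estimated correlation). Of 16 Notch pathway genes 5 rose and 0 fell (5 and 1 when adjusted over the list alone), among them the ligand Delta (1.72 ± 0.15, edgeR adjusted p = 3.56e-07), N (1.10 ± 0.16) and the neuroblast target E(spl)mgamma-HLH (1.42 ± 0.18; list camera adjusted p = 0.00962; adjusted p = 0.147 with an estimated correlation). The early larval temporal factors had 3 rises of 6 and 0 falls (4 and 1 when adjusted over the list alone; camera adjusted p = 0.011; adjusted p = 0.27 with an estimated correlation).

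Neuron function genes fell, 14 of 23 with 0 rises (18 and 0 when adjusted over the list alone), and 0 lay above WT. Sh, a potassium channel, went from 967.8 ± 77.6 to 161.2 ± 22.5 CPM (-2.59 ± 0.15, edgeR adjusted p = 2.23e-09), VAChT fell by 2.25 and unc-13 by 1.01 on the log2 scale (SE 0.20 and 0.11). The list median was -0.84 (camera adjusted p = 7.08e-20; adjusted p = 0.0362 with an estimated correlation). Of 9 ganglion mother cell and commitment genes 4 fell and 2 rose (5 and 2 when adjusted over the list alone), with fne, an ELAV family protein, at -0.84 ± 0.12 (camera adjusted p = 0.00519; adjusted p = 0.147 with an estimated correlation). These include the mutated nerfin-1 itself. Without it and lola, 3 of 7 fell and 1 rose (4 and 1 over the list alone; camera adjusted p = 0.00416; adjusted p = 0.136 with an estimated correlation). Medulla neuron identity factors moved both ways, with 7 of 19 falling, including ap, pdm3 (-0.73 ± 0.16) and vvl (-1.10 ± 0.26), and 3 rising (8 and 4 when adjusted over the list alone; camera adjusted p = 0.107). Of 21 axon guidance and adhesion genes 4 fell by either adjustment, among them the adhesion protein Fas2 (-0.95 ± 0.13; camera adjusted p = 0.162).

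Among the medulla temporal factors hth fell by 0.88 (SE 0.12, edgeR adjusted p = 6.62e-05) and ey, which follows hth in the series, rose (1.18 ± 0.26, edgeR adjusted p = 0.00475). In all 3 of 13 rose and 1 fell (6 and 1 when adjusted over the list alone). The list was not called (camera adjusted p = 0.0524). It was called without any 1 of the 3 lola[E76] libraries or without nerfin-1[159] replicate 2 (0.0141 at the lowest). Of 12 late temporal and ecdysone genes 4 fell and 1 rose (6 and 1 when adjusted over the list alone), including Eip93F (-1.07 ± 0.21) and Eip74EF (-2.62 ± 0.51, edgeR adjusted p = 0.00158, and 0.105 with limma voom). This list had camera adjusted p = 0.107 (0.0364 without nerfin-1[159] replicate 1).

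Of 18 S phase genes 8 rose and 0 fell (12 and 0 when adjusted over the list alone), all 18 above WT, including E2f1 (0.87 ± 0.11, edgeR adjusted p = 1.57e-05) and the chromatin assembly subunit Caf1-180 (1.25 ± 0.25; list camera adjusted p = 1.06e-09; adjusted p = 0.147 with an estimated correlation). Of 19 G2 and mitosis genes 9 rose and 0 fell (10 and 0 when adjusted over the list alone), all 19 above WT, among them CycA (1.29 ± 0.15), the phosphatase stg (0.98 ± 0.15) and Incenp (1.5 ± 0.25; list camera adjusted p = 1.46e-08; adjusted p = 0.147 with an estimated correlation). Of 16 nucleolus and growth genes 2 rose by either adjustment (camera adjusted p = 0.0315; adjusted p = 0.27 with an estimated correlation). This list call was lost without WT replicate 1 or nerfin-1[159] replicate 2 (up to 0.139). Of 12 glycolysis genes 4 rose (4 rises and 2 falls over the list alone), including Ldh, PyK (1.19 ± 0.18) and Hex-A (0.70 ± 0.15; list camera adjusted p = 0.0323; adjusted p = 0.344 with an estimated correlation). This list call was lost without WT replicate 1 or nerfin-1[159] replicate 1 or 2 (up to 0.0865). Of 18 oxidative phosphorylation genes 0 were called by either adjustment (camera adjusted p = 0.647).

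Of 11 JNK, damage and cell death genes 3 rose (4 when adjusted over the list alone), including the TNF ligand egr (1.43 ± 0.24) and GstD1 (1.3 ± 0.27; camera adjusted p = 0.00962; adjusted p = 0.131 with an estimated correlation). Of 12 heat shock genes 4 fell by either adjustment, among them Hsp23 (-0.84 ± 0.16), with the Hsp70 copies again uncertain (camera adjusted p = 0.00519; adjusted p = 0.344 with an estimated correlation). This list call was lost without WT replicate 3 or nerfin-1[159] replicate 2 (up to 0.122). Of 9 neuroepithelium and lamina genes 3 fell (4 when adjusted over the list alone), led by sim, a factor of lamina neurons and midline cells (-4.69 ± 0.60, from 19.2 to 0.722 CPM; -4.10 without nerfin-1[159] replicate 2 and -6.01 without replicate 3), and sdt, an apical polarity protein (-0.92 ± 0.17; camera adjusted p = 0.00962; adjusted p = 0.131 with an estimated correlation). Like ry, sim lies in the run of large falls on 3R, so the same candidate variant applies to it. This list was not tested again without sim.

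Of 10 glial genes 0 were called by either adjustment (camera adjusted p = 0.915, median -0.20 with the test above 0). Of 4 eye disc genes elB fell (-1.12 ± 0.15), 1 by either adjustment (camera adjusted p = 0.224). Col4a1 was the 1 haemocyte and fat body gene of 4 that rose, by either adjustment (camera adjusted p = 0.321, median -0.31 with the test above 0). Both roX RNAs, which are made mainly in males, rose, roX2 by 1.07 ± 0.19 (edgeR adjusted p = 0.000545) and roX1 by 0.72 ± 0.19 (edgeR adjusted p = 0.0156), 2 of 2 by either adjustment (camera adjusted p = 0.005; adjusted p = 0.147 with an estimated correlation). The roX1 call was lost without WT replicate 1 or 2 or nerfin-1[159] replicate 1 or 3 (up to 0.0891), and with the DESeq2 Wald test (0.0985). A difference in sex makeup between WT and nerfin-1[159] libraries stays open.

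**Figure D2:**
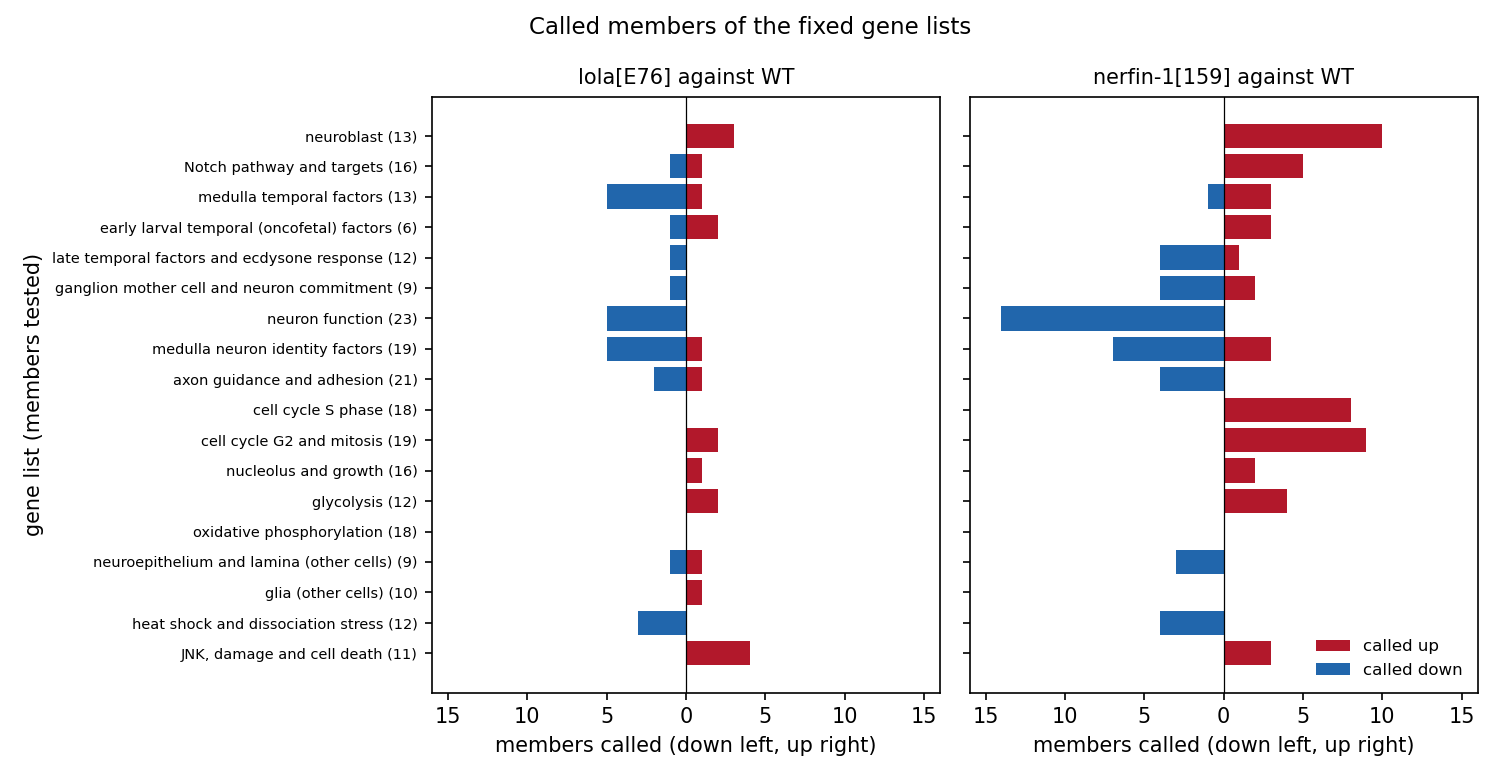
Number of members called lower (bars to the left) or higher (bars to the right) than WT for 18 of the fixed gene lists, in lola[E76] and nerfin-1[159] clones, with the number of members tested in brackets. Of 23 neuron function genes 5 were lower in lola[E76] and 14 in nerfin-1[159] clones.

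The third comparison tested both mutant genotypes against each other. The lola[E76] columns are named after a 2R recombination site and the nerfin-1[159] columns after a 3L site. Clone arm and genotype therefore differ together in this contrast, and the candidate variant on 3R applies to ry and sim here too. chinmo was higher in lola[E76] than in nerfin-1[159] clones (0.58 ± 0.12, edgeR adjusted p = 0.00156), as were Imp (1.17 ± 0.24, edgeR adjusted p = 0.00161) and pros (0.83 ± 0.16, edgeR adjusted p = 0.000995). Syp (-0.76 ± 0.14, edgeR adjusted p = 0.000616) and the neuroblast genes klu (-2.12 ± 0.31), insc (-1.80 ± 0.29) and dpn (-1.43 ± 0.44, edgeR adjusted p = 0.0323) were lower in lola[E76] clones. The dpn call was lost without any 1 of the 3 lola[E76] libraries or without nerfin-1[159] replicate 1 or 3 (up to 0.105). lola itself was lower (-0.37 ± 0.10, edgeR adjusted p = 0.0168). This call was lost without lola[E76] replicate 3 or nerfin-1[159] replicate 2 or 3 (up to 0.0978). nerfin-1 was higher by 3.95 ± 0.36 (4.94 without nerfin-1[159] replicate 1). elav differed by -0.10 ± 0.10 (edgeR adjusted p = 0.622). The largest differences under the naming rule were of jef (6.37 ± 0.60), ry (6.17 ± 0.59), the potassium channel Shab (5.24 ± 0.35) and betaTub60D (4.48 ± 0.37), higher in lola[E76] clones, and of Actbeta (-4.07 ± 0.70), the monoamine transporter Vmat (-3.67 ± 0.41), Rnf11 (-3.27 ± 0.24) and Col4a1 (-3.01 ± 0.28). Without nerfin-1[159] replicate 2, jef was at 9.39, betaTub60D at 5.10 and ry at 5.57, and without nerfin-1[159] replicate 1 ry was at 0 in that genotype (at least 121-fold higher in lola[E76] clones). Without lola[E76] replicate 3, Vmat was at -4.35 and Actbeta at 0 in lola[E76] clones (at least 67.2-fold lower), and without lola[E76] replicate 2 Actbeta was at -3.47.

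In this contrast 1156 genes were called, 639 higher and 517 lower in lola[E76] clones, of which 397 and 261 differed at least 2-fold. Libraries lay wholly apart for 30.4% of tested genes, against 10% by chance, and for 1126 of the called genes. The lower genes included 28 histone copies. Neuroblast (0 higher and 4 lower of 13 by either adjustment, camera adjusted p = 0.000625; adjusted p = 0.122 with an estimated correlation) and Notch pathway genes (0 and 5 of 16, 0 and 6 over the list alone, camera adjusted p = 0.000507; adjusted p = 0.122 with an estimated correlation) were lower in lola[E76] clones, with Delta at -1.35 ± 0.15 and E(spl)mgamma-HLH at -1.35 ± 0.18. So were medulla temporal factors (1 and 9 of 13 by either adjustment, median -1.38, camera adjusted p = 0.000507; adjusted p = 0.238 with an estimated correlation), with hbn at -1.69 ± 0.21, slp2 at -1.88 ± 0.26 and hth opposite at 1.68 ± 0.12. Neuron function genes were higher (14 and 2 of 23, 16 and 2 over the list alone, camera adjusted p = 1.69e-06; adjusted p = 0.211 with an estimated correlation), with Sh at 2.00 ± 0.14, Rab3 at 1.89 ± 0.26 and futsch at 1.08 ± 0.13. G2 and mitosis genes were lower (0 and 3 of 19, 0 and 5 over the list alone, camera adjusted p = 0.000895; adjusted p = 0.359 with an estimated correlation), with stg at -1.40 ± 0.15.

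S phase genes (0 and 2 of 18, 0 and 1 over the list alone) gave camera adjusted p = 0.0309 (adjusted p = 0.566 with an estimated correlation). This call was lost without lola[E76] replicate 2 or 3 or nerfin-1[159] replicate 1 or 3 (up to 0.0781). Oxidative phosphorylation genes (1 and 0 of 18 by either adjustment, COX6B at 0.50 ± 0.13) gave camera adjusted p = 0.0444 (adjusted p = 0.359 with an estimated correlation). This call was lost without lola[E76] replicate 1 or 3 or nerfin-1[159] replicate 2 (up to 0.129). Commitment genes (4 and 2 of 9 by either adjustment, tap at -1.49 ± 0.18) were not called (camera adjusted p = 0.106), but were without WT replicate 2 or nerfin-1[159] replicate 2 (0.0383 at the lowest). Without nerfin-1 and lola, 3 of 7 were higher and 1 lower by either adjustment (camera adjusted p = 0.115). The remaining lists were not called. Higher and lower members over all genes, then over the list alone, were 2 and 2, then 3 and 3, for early larval factors (mamo -0.75 ± 0.11, svp -1.05 ± 0.19, camera adjusted p = 0.981). They were 3 and 1, then 3 and 2, for late temporal genes (Eip74EF 3.84 ± 0.51, camera adjusted p = 0.44). They were 2 and 8, then 6 and 9, for identity factors (ap 3.28 ± 0.30, Drgx -2.29 ± 0.27, camera adjusted p = 0.115). For axon guidance genes they were 4 and 3, then 4 and 4 (DIP-alpha 1.37 ± 0.22, Nrt -0.90 ± 0.14, camera adjusted p = 0.994). Nucleolus genes had 1 and 0 by either adjustment (Nopp140 1.19 ± 0.22, camera adjusted p = 0.641). Glycolysis genes had 1 and 3, then 1 and 4 (Eno 0.80 ± 0.13, camera adjusted p = 0.284). Neuroepithelium and lamina genes had 3 and 1, then 4 and 1 (sim 4.81 ± 0.60, 4.22 without nerfin-1[159] replicate 2 and 6.13 without replicate 3; camera adjusted p = 0.106). Glial genes had 2 and 1 by either adjustment (wrapper 3.63 ± 0.80, 4.46 without nerfin-1[159] replicate 3; camera adjusted p = 0.844). Eye disc genes had 1 and 0, then 2 and 0 (elB 0.70 ± 0.15, camera adjusted p = 0.151). Haemocyte and fat body genes had 0 and 1 by either adjustment (Col4a1, camera adjusted p = 0.115, median 0.31 with the test below 0). Heat shock genes had 2 and 0 by either adjustment (camera adjusted p = 0.481). For JNK, damage and cell death genes the numbers were 3 and 2 by either adjustment (puc 0.99 ± 0.18, camera adjusted p = 0.287). The roX RNAs had 0 and 0, then 0 and 2 (camera adjusted p = 0.106, and 0.0258 without lola[E76] replicate 1). Several copies of Su(Ste), a Y-linked repeat, were among the genes called lower in lola[E76] clones. Over the libraries of each genotype, Su(Ste):CR42415 held 0 counts in lola[E76] against 138 in nerfin-1[159], and Su(Ste):CR42444 0 against 90. A difference in sex makeup between the mutant libraries therefore stays open too.

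The responses to both mutations were then compared. Of the genes called against WT, 92 rose and 62 fell in both genotypes, where independent lists of these sizes share 15.1 and 13.6, and 41 were called in opposite directions (26 higher and 15 lower in lola[E76] clones, against 16.7 and 12.3 in independent lists). Both comparisons use the same WT libraries, whose error enters both. Leaving out WT replicate 1 or WT replicate 2 reduced the 154 genes called in the same direction to 85 and 87. Imp, wor, ase and N were among the shared rises, and nSyb, unc-13, VAChT and Eip93F among the shared falls. Across all tested genes, which are not independent replicates, the log2 differences correlated at Pearson's r = 0.28 (covariance 0.277), while 50 simulations of unchanged groups gave r of 0.44 to 0.55 (covariance 0.136 to 0.182). Unchanged groups lack the spread of real responses, so their r is no yardstick for the r of 0.28, which alone shows no likeness. The covariance lay above every simulated value. The simulations gave each gene the same dispersion in all genotypes, although WT libraries varied least, so the shared WT error is not exactly matched. When each mutant was compared with WT libraries of its own, 1 for one mutant and 2 for the other in all 6 ways, r was 0.14 to 0.18 and the covariance 0.163 to 0.246. Those fits shared 29 to 71 calls of the same direction, where independent lists share 4.2 to 11.8, and had 9 to 21 calls of opposite direction. Of the 154 genes 44 also differed between the mutants.

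**Figure D3:**
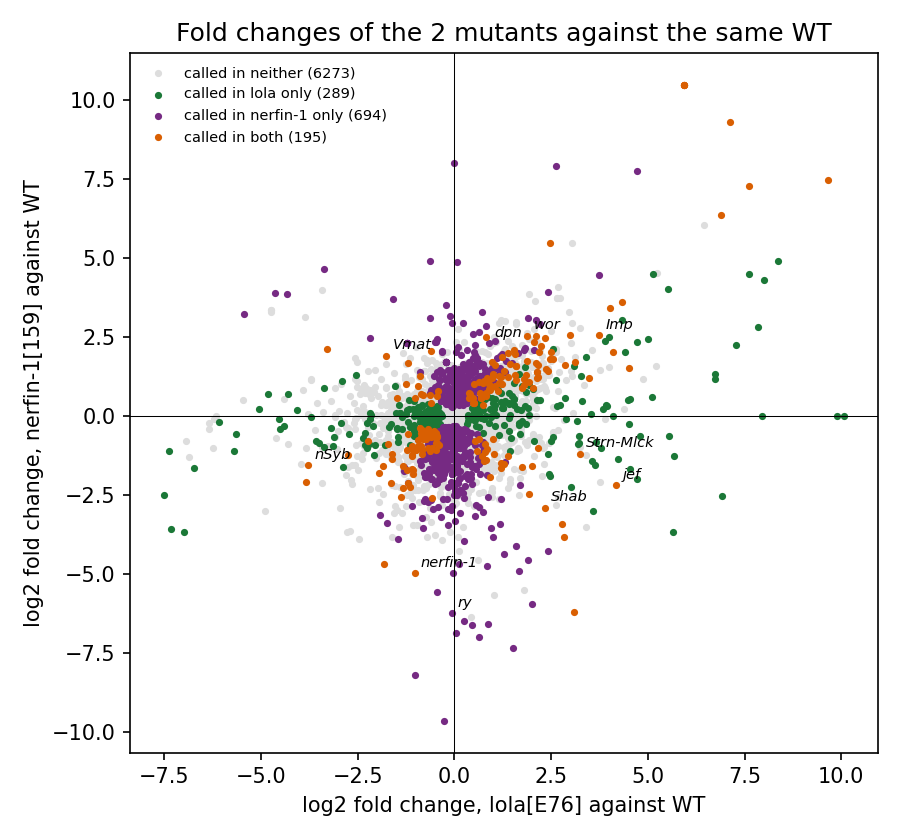
Log2 difference from WT in lola[E76] clones (x axis) against nerfin-1[159] clones (y axis) for the 7451 tested genes, 1 point per gene, coloured by where they were called. The 154 genes called in the same direction and the 41 called in opposite directions lie in different quadrants, and fitted values of genes at 0 counts in a genotype depend on the prior count.

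The DamID data asked where Lola.N contacts chromatin. The authors' lists held 4676 peaks over 4.84 Mb in N1 (median width 809 bp) and 4544 peaks over 4.94 Mb in N2 (832 bp), each called against Dam alone. Of N1 peaks 70.7% overlapped an N2 peak by at least 1 bp and of N2 peaks 72.9% an N1 peak, against means of 7.0% and 7.2% in 1000 shuffles of peaks within chromosomes, where the highest were 8.3% and 8.5% (permutation p = 0.000999, the smallest they can give). Peaks of both replicates formed 3342 intervals, and 3415 of 17537 genes with coordinates held such an interval in the gene or within 1 kb of it. Scores are the authors' own values for each peak. The 5 peaks with the highest mean of both scores lay at GluClalpha and the overlapping lncRNA:CR43488 on 3R (19743741 to 19744560, N1 score 7.8 and N2 score 6.21), lncRNA:acal on 2R (10548133 to 10548920), arg on X (525519 to 526218), ImpL2 and the overlapping CG46460 on 3L (4227007 to 4227508) and caps on 3L (13254602 to 13255508), in coordinates of Release 6 of the genome.

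Every gene fixed for description held a peak of both replicates. There were 6 intervals at lola, 1 at nerfin-1 (3L, 913228 to 914086, N1 score 3.65), 4 at chinmo, 9 at Imp, 8 at Syp, 2 at dpn (2R, 8232706 to 8234809, N1 score 5.75), 9 at pros and 2 at elav. Of genes higher in lola mutant clones, wor, ase, N and hth had 2, 2, 5 and 6. Both klu and Delta, which rose in nerfin-1 mutant clones but were not called in lola mutant clones, had 3. Of genes lower in lola mutant clones, nSyb and Ets65A had 2 each, and qvr, Lcch3 and Lim1 had 1 each. No such interval lay at jef, betaTub60D, Actbeta, Ca-alpha1D, kn, ry or sim. The reference carried no strand, so peaks before and after a gene were counted alike.

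Genes that rose in lola[E76] clones held Lola.N peaks more often than other tested genes, 136 of 264 (51.5%) against 28.3% of all 7442 with coordinates (odds ratio 2.81, 95% interval 2.19 to 3.60, Fisher's exact test, two-sided, p = 8.17e-16). Bound genes were longer (median 5075 against 2734 bp), and within bins of expression and gene length the odds ratio was 2.29 (1.78 to 2.95). Genes that rose in nerfin-1[159] clones were bound in 203 of 416 cases (48.8%; 2.57, 2.10 to 3.13, Fisher's exact test p = 1.16e-19; 2.29, 1.85 to 2.83, within bins). Genes that fell in lola[E76] clones were bound in 96 of 217 cases (44.2%; 2.06, 1.57 to 2.70, Fisher's exact test p = 3.59e-07), with 1.35 (1.01 to 1.81) within bins, 1.26 (0.925 to 1.72) for peaks within 1 kb of a gene end and 1.40 (1.00 to 1.95) for the higher-scoring peaks (at or above the median score of their list). Genes that fell in nerfin-1[159] clones were bound in 149 of 467 cases (31.9%; 1.20, 0.982 to 1.47, Fisher's exact test p = 0.0798). For these the odds ratio turned to 0.595 (0.477 to 0.742) within bins and 0.624 (0.48 to 0.81) near gene ends, and was 1.27 (1.05 to 1.54) with N1 peaks alone and 1.48 (1.18 to 1.87) for the higher-scoring peaks.

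**Figure D4:**
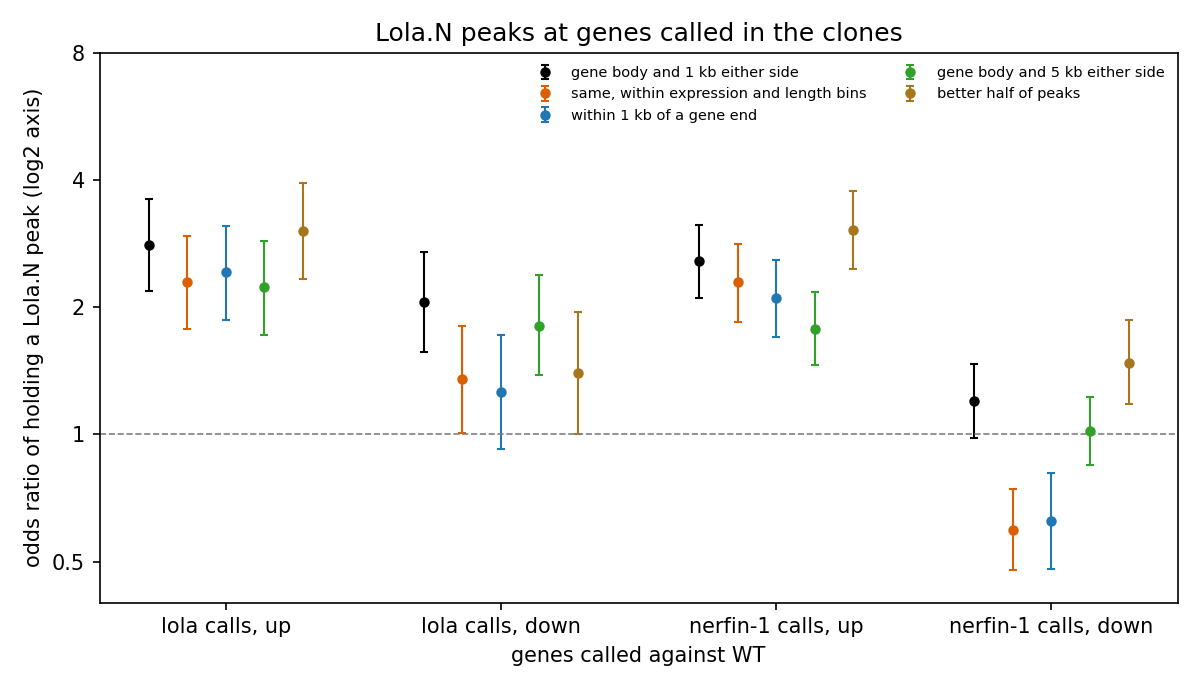
Odds ratio of holding a Lola.N peak of both replicates for genes called higher or lower in each mutant against other tested genes, on a log2 axis with 95% intervals, for 5 ways of assigning peaks or comparing genes. Rises lie at 2.81 and 2.57 by gene body and 1 kb either side and at 2.29 and 2.29 within bins, while falls in nerfin-1[159] clones go from 1.20 to 0.595.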

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

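The comparison of genes with opposite effects in both mutants was planned, while the arm values for rises and falls apart were chosen only after the result was seen.

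7 of the named genes were called in opposite directions against WT in the 2 mutant genotypes, which nearly ensures a call in the direct contrast, so its p-values add no separate evidence. Differences are lola[E76] minus nerfin-1[159] (log2, n = 3 each). The homeodomain factor hth was higher in lola[E76] (0.80) and lower in nerfin-1[159] clones (-0.88), a difference of 1.68 (edgeR adjusted p = 2.55e-08). The same direction held for jef (4.19 and -2.18, difference 6.37, edgeR adjusted p = 4.88e-07), the potassium channel Shab (2.33 and -2.90, difference 5.24, edgeR adjusted p = 1.14e-08) and the kinase gene Strn-Mlck (3.25 and -1.20, difference 4.44, edgeR adjusted p = 2.4e-13). The reverse held for the homeodomain factor Drgx (-1.26 and 1.03, difference -2.29, edgeR adjusted p = 5.74e-06), the temporal factor slp2 (-0.93 and 0.95, difference -1.88, edgeR adjusted p = 5.34e-05) and the monoamine transporter Vmat (-1.76 and 1.91, difference -3.67, edgeR adjusted p = 3.41e-06). The slp2 call in nerfin-1[159] clones was lost without WT replicate 2, WT replicate 3 or nerfin-1[159] replicate 3 (adjusted p up to 0.101), and that in lola[E76] clones without any library but lola[E76] replicate 2 (up to 0.176). The Drgx call in nerfin-1[159] clones was lost without nerfin-1[159] replicate 1 or 3 (up to 0.0703). The jef call there was lost without any library but WT replicate 1, lola[E76] replicate 1 and nerfin-1[159] replicate 2 (up to 0.225), so the opposite direction is weak for these 3 genes. Without nerfin-1[159] replicate 2, jef was at -5.20 in nerfin-1[159] clones with a difference of 9.39, and without WT replicate 2 at 4.80 and -1.57. Without lola[E76] replicate 3, Vmat was at -2.44 with a difference of -4.35. Groups of 3 are too small for a search for single deviating libraries.

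Splitting the 6 libraries of a contrast into 3 and 3 in other ways left the real split as 1 of 10 in each contrast. The real splits gave 475 genes for lola[E76] against WT, 999 for nerfin-1[159] against WT and 1033 between the mutants, and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.

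The WT columns are named after a 2R recombination site and the nerfin-1[159] columns after a 3L site, so clone arm and genotype differ together. Called genes of nerfin-1[159] against WT lay on 3L and 2R with an odds ratio of 1.04 (0.898 to 1.20), which argues against a general excess of pooled rises and falls. Without histone copies, rises of any size had 1.37 (1.08 to 1.74) on 2R and 1.15 (0.896 to 1.47) on 3L, and falls 0.925 (0.728 to 1.18) and 0.902 (0.708 to 1.15). Pooling also hides unequal arms among rises of at least 4-fold, which were more frequent on 3L (2.04, 1.23 to 3.38) and 2L (2.45, 1.49 to 4.03) and less frequent on 2R (0.459, 0.21 to 1.00) and 3R (0.313, 0.135 to 0.723). Without the near-identical histone copies, which share reads, 2L was at 1.14 (0.589 to 2.21), 3L at 2.83 (1.66 to 4.84), 2R at 0.578 (0.261 to 1.28) and 3R at 0.393 (0.168 to 0.917). An effect of the clone arm on rises, and variants at single genes, stay open.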

How the results depend on the processing

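The alternatives for calls, lists and peaks were planned, and no test here was chosen only after the result was seen.

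Leaving out 1 library gave 315 to 497 called genes for lola vs WT calls, 593 to 1008 for nerfin-1 vs WT calls and 889 to 1135 for lola vs nerfin-1 calls, with 85 to 152 shared calls, r of 0.23 to 0.40, 27 to 33 list calls and 150 to 154 of the 166 named calls. The lowest counts of lola[E76] calls, 315, came without WT replicate 1 and without WT replicate 2, where shared calls fell to 85 and 87. Other scalings, filters and tests gave 470 to 673 lola vs WT calls, 840 to 1048 nerfin-1 vs WT calls and 1033 to 1371 lola vs nerfin-1 calls. With no filter r was 0.39, and 29 of the 31 list calls were lost when the correlation was estimated, leaving 2. With the fry test 9 list calls were lost and 8 gained. For lola vs WT it lost medulla temporal, commitment and oxidative phosphorylation genes (fry adjusted p = 0.0782 each). It also lost S phase (0.164), G2 and mitosis (0.32) and heat shock genes (0.348) there. The replicate block lost G2 and mitosis genes in that contrast as well (camera adjusted p = 0.052). The cause of these shifts was not tested.

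Peaks at or above the median score numbered 2351 in N1 and 2285 in N2. Overlap was 56.4% and 58.0% when 0.5 of each peak had to be covered and 74.8% and 76.9% among the higher-scoring peaks. For genes that fell in lola[E76] clones the odds ratio of a peak was 1.26 near gene ends and 1.40 for these. For genes that fell in nerfin-1[159] clones it was 1.27 with N1 alone and 1.48 for the higher-scoring peaks, and reversed to 0.624 near gene ends and 0.595 within bins of expression and length. The cause of either reversal was not tested.

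The replicate block gave 431 lola vs WT calls, 820 nerfin-1 vs WT calls and 1080 lola vs nerfin-1 calls, of which 414, 792 and 1048 were among the calls without it, 135 shared calls and r of 0.30. No named gene that was called changed direction in any setting run. Of those not called, Syp in lola vs WT reached 0.12, and ATPsynC (-0.01) and elav in nerfin-1 vs WT changed sign when 1 library was left out.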

Other observations

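The muscle, 3R and bound-rise tests, the lists of bound genes against random lists, arms other than for nerfin-1[159] calls and the genes named in the next paragraph were chosen only after the result was seen.

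Further genes were called in opposite directions in both mutants. As log2 differences from WT, the glutamate-gated chloride channel GluClalpha was higher in lola[E76] (0.84) and lower in nerfin-1[159] clones (-1.06), as were the Wnt receptor fz2 (0.59 and -1.12), the dense core vesicle protein IA-2 (1.40 and -1.26) and Cipc (1.93 and -2.46). These calls held whichever library was left out.

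Lola.N peaks lay at 12 of 13 tested neuroblast genes (4.3 expected from 10000 random lists matched in expression and gene length; permutation adjusted p = 0.0042), 12 of 16 Notch pathway genes (4.5; 0.0042), 10 of 13 medulla temporal factors (4.5; 0.0168) and 8 of 12 glycolysis genes (3.1; 0.0304). They also lay at 6 of 6 early larval temporal factors (2.7; 0.0403), 10 of 12 late temporal genes (5.6; 0.0456) and 8 of 9 commitment genes (4.1; 0.0456). Of 23 neuron function genes 13 held a peak (11.7 expected; 0.904). By arm, genes that rose in lola[E76] clones were more frequent on 2R (odds ratio 1.5, 1.13 to 1.98), genes that fell there more frequent on chromosome 4 (3.55, 1.69 to 7.45; 8 of 85 tested genes), and genes that rose in nerfin-1[159] clones less frequent on X (0.523, 0.381 to 0.719, and 0.566, 0.411 to 0.779, without histone copies). Rises of at least 4-fold in lola[E76] clones had 1.93 (1.28 to 2.90) on 2R, and 2.03 (1.34 to 3.07) without histone copies. Variants linked to lola[E76] on that arm stay open.

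Genes that rose in either mutant often held Lola.N peaks. Gene length and expression as the whole cause are argued against by an odds ratio of 2.29 within bins for lola[E76] rises. Rises called in both mutants had 4.57 (2.88 to 7.24), and those not called up in the other mutant 1.62 (1.19 to 2.20) in lola[E76] and 1.81 (1.43 to 2.31) in nerfin-1[159] clones. For lola[E76] rises with a nerfin-1[159] difference at or below 0 it was 1.38 (0.885 to 2.15, 85 genes). The mirror set of nerfin-1[159] rises had 1.58 (1.07 to 2.33, 130 genes), with an interval that overlaps widely. Most of the differences at or below 0 were not called, so shared rises can fall in either set. These sets therefore cannot tell whether binding goes with shared rises alone. Direct repression by Lola.N and open chromatin of progenitors stay open.

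Of 36 genes on a muscle list drawn up after such rises were seen, 14 had too few counts to be tested. Of the other 22, 10 rose in lola[E76] clones (6 contractile and 4 other muscle genes) and 0 fell, against 267 rises among all 7451 genes. Mlc2 was at 432 counts against 16 and Prm at 366 against 0 (at least 127-fold higher). The troponin T gene up rose by 5.67 (log2, edgeR adjusted p = 5.36e-07). In nerfin-1[159] clones bt (1.64), how (1.08) and Mef2 (0.99, lost without WT replicate 1 or 3 or any nerfin-1[159] library, adjusted p up to 0.149) rose, the latter pair in both mutants, and Strn-Mlck (-1.20) and kirre (-0.73) fell. Muscle cells in the sorted samples cannot be told apart from expression in neurons. In lola[E76] libraries Mhc held 13 counts (5 in WT) and Act57B 5 (29 in WT). Together they stayed at or below 2.22% of the summed CPM of up, wupA, Prm and Mlc2, but their share in muscle was not measured here. TpnC47D, TpnC25D, TpnC4, Mlp60A and fln were at 0 counts in every genotype, so they do not separate lola[E76] clones from WT. Other contractile genes, untested or not called, went both ways from WT to lola[E76] clones. Act87E (0 to 32 counts), TpnC73F (2 to 21), Mlc1 (6 to 38) and Mp20 (3 to 16) were higher. Mf (47 to 16) and sls (108 to 63) were lower. Direct Lola.N binding at the muscle genes that rose cannot be told apart from none, with peaks at 4 of 10 and an odds ratio of 1.69 (0.477 to 6.0; Fisher's exact test p = 0.483). No enrichment was tested, since the list followed the rises.

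Large falls in nerfin-1[159] clones lay close together on 3R, where 6 of 39 falls of at least 8-fold (ry, sim, Cyp6d5, CG14855, CG6912 and asRNA:CR45600) lay within 100 neighbouring tested genes. This is the highest number in any such window, where a single window holds 0.52 on average. The highest number in 10000 permutations reached 7 (permutation p of the highest number = 0.0042). The test followed the observation, so this p is descriptive. CG6912 went from 319 counts to 0, at least 87-fold lower, while the CG14855 call was lost without any 1 WT library, lola[E76] replicate 2 or nerfin-1[159] replicate 1 or 2 (adjusted p up to 0.109). A variant on 3R in the nerfin-1[159] stock is a candidate explanation. Recombination at a 3L site leaves 3R as in the parent cell, so such a variant would have to lie on both 3R chromosomes to bring counts to 0. A variant of the WT stock alone is argued against by lola[E76] clones, which differed from WT by at most 2.02-fold at these genes. Neighbours regulated together, and a haplotype that WT and lola[E76] stocks share, stay open.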
